A study of Mus musculus with 12 samples.

How the data were processed

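RNA sequencing was used to compare bone marrow macrophages of healthy mice with those of mice carrying late-stage leukemia grown from transplanted cells of a blast-crisis chronic myeloid leukemia model (bcCML). Per the labels, cells were sorted as CD45+, F4/80+, Ly6g- and Ly6c-, RNA was extracted with a column kit, and 1 ng was amplified as full-length cDNA before tagmentation. The amplification kit marks neither strand nor single molecules, so antisense and overlapping genes could not be separated and intervals from counts cover counting error only. The deposited values are raw counts per gene from the authors, with 1 column per library and no normalization. The submitters' processing notes name bcl2fastq 2.19.1, fastp 0.23.1, STAR 2.7.9a, Subread 2.0.1, featureCounts, DESeq2 1.28.1 and R 4.0.2 with the mouse build GRCm39, and give no order or settings for them. The count table had 56832 gene entries, of which 1544 carried an Ensembl identifier in place of a symbol and 27619 had no count in any library. The authors' own test results were not used here.

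The 12 libraries were grouped by the sex and condition in their labels, with 3 libraries in each of 4 groups. Total counts per library ran from 16911827 to 30014855. A count of 0 allows up to 3 counts per library, which is 0.1 to 0.177 CPM (counts scaled by the library total) at these depths. The Wilson 95% interval of a gene list's share of 1 library's counts was at most 4.52% of that share wide on either side. The labels do not say whether replicates were separate animals, so every p measures the spread between libraries. No library was a copy of another: the lowest chi-square per degree of freedom between 2 libraries of a group was 22.6.

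Genes were filtered with filterByExpr of edgeR over the 4 groups, which left 15758 genes, and counts were scaled by the trimmed mean of M values (TMM). CPM were computed here from the total counts, with a prior count of 2 where they were taken to the log2 scale. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion in R 4.3.3. The main comparison, leukemic against non-leukemic, used all 12 libraries with sex as a term. The effect in each sex, the interaction of sex and leukemia and the sex difference in each condition were contrasts of a model with 4 group means. P values were adjusted by Benjamini and Hochberg over the genes tested, and an adjusted p under 0.05 counted as passed. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Every test was two-sided unless said otherwise.

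A set of 27 gene lists for metabolism, macrophage states and other cell types that the gate could hold was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists. Each list was tested again with a correlation estimated from the data and with fry, which asks whether the genes of a list move one way on balance. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. The summed share of counts of each list was compared between conditions by an exact permutation test over the 924 arrangements of 12 libraries, whose smallest p is 0.00216, with p adjusted over the lists. In all, 6 list genes were missing from the table under the symbols used.

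Genes named in the text follow a rule. It takes the 12 largest positive and 12 largest negative log2 fold changes of the main comparison among genes that passed, had a mean log2 CPM of at least 4 and had all leukemic libraries on 1 side of all non-leukemic libraries. Predicted genes, Y-linked genes and Xist were left out there. It takes up to 5 genes per direction with the lowest p in every other comparison, and the 4 members with the lowest p of each list. Hcar1, Slc16a1, Slc16a3, Ldha, Mrc1, Arg1, Nos2, Cd274, Ccl3, the gate genes Ptprc, Adgre1, Ly6g, Ly6c1 and Ly6c2, and the sex genes Xist, Ddx3y, Uty, Kdm5d and Eif2s3y were named whatever their values. Other list members are named only as members of their list, chosen after their values were seen. The groups, tests, lists, naming rule and all alternatives but the last named below were fixed before the data were examined.

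The alternatives were relative log expression (RLE) size factors, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a filter of 5 CPM in 3 libraries, a test against a minimum change of 1.5-fold, no sex term, the replicate number as a block, a fit of only the libraries compared, and leaving out each library in turn. A fit without female leukemic replicate 1 and male non-leukemic replicate 3 was added after seeing the data. The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For the main comparison edgeR recovered 66% and 92% of them over 15220 genes, and 4.82% of its 166 calls were false. In the same simulation DESeq2 recovered 80% and 98% with 20.9% of its calls false, and limma-voom recovered 64% and 91% with 4.32% false. Within males, edgeR recovered 19% of the 2-fold and 76% of the 4-fold changes, and within females 29% and 81%. For the interaction it recovered 6% and 55%, for the sex difference without leukemia 23% and 82%, and with leukemia 19% and 80%. The simulated counts had no library standing apart, and group means were equal but for the planted changes. These shares therefore need not hold for the real libraries. A planted 2-fold rise of the glycolysis list was found by camera in both list comparisons, with 0 other lists called. Chromosome order of genes was taken from a RefSeq table of GRCm38.p6, and no coordinates are given, since the counts rest on GRCm39.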

Results

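Gene expression was measured by RNA sequencing in macrophages sorted from mouse bone marrow, with 3 libraries each from male non-leukemic, female non-leukemic, male leukemic and female leukemic mice. The leukemic libraries were made at day 11. The series title concerns lactate, macrophage polarization and GPR81, the lactate receptor encoded by Hcar1, in the marrow of acute myeloid leukemia. Total counts were 16911827 to 26611831 in the non-leukemic and 22437689 to 30014855 in the leukemic libraries, and 15758 of 56832 genes were tested. Across genes, Spearman correlations within a group were 0.934 to 0.985. The first principal component held 32.1% of the variance, with non-leukemic libraries between -76.0 and -36.7 and leukemic libraries between 30.2 and 100.2. Female leukemic replicate 1 stood apart, with 17891 genes detected against 19521 to 21247 in the other libraries and a median Spearman correlation of 0.915 with the others, which themselves had medians of at least 0.943. Male non-leukemic replicate 3 stood apart on the third component, at 84.2, and had 258 CPM of Adgre1, the gene of the sorted antigen F4/80, against 75.9 to 112 in the other non-leukemic libraries.

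**Figure D1:**
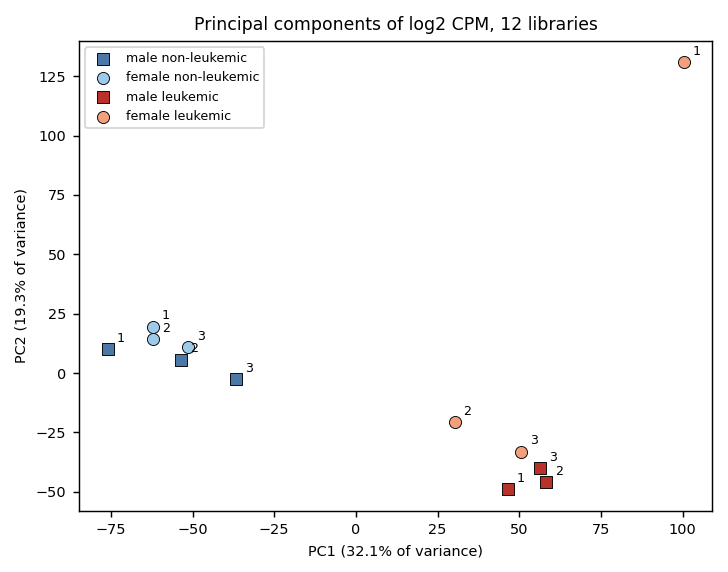
Each point is a library, placed by its first and second principal components of log2 CPM, which hold 32.1% and 19.3% of the variance. Colours mark the 4 groups, squares are males, circles are females and the number is the replicate. Female leukemic replicate 1 lies at 131 on the second component.

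Leukemic and non-leukemic libraries were compared to ask how marrow macrophage transcripts differ in late leukemia. Genes of red cell precursors were lower in the leukemic libraries: all 13 tested fell, with a median log2 fold change of -4.16 (n = 6 per condition). Genes of T and NK cells were higher: all 13 tested rose, with a median of 2.39. Among macrophage genes, 14 of 22 tested markers of marrow resident macrophages fell. Of 25 interferon response genes, which many cell types express, 12 rose. With edgeR, 2822 of 15758 genes passed, of which 1373 were higher and 1449 lower in leukemic libraries, and the median log2 fold change of all genes tested was -0.01. Of the genes tested, 1368 had all 6 libraries of a condition above all 6 of the other, where chance gives 34.1. Against a minimum change of 1.5-fold, 978 genes passed. Without female leukemic replicate 1 and male non-leukemic replicate 3, a choice made after seeing the data, the count was 4717, with 2421 higher and 2296 lower.

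**Figure D2:**
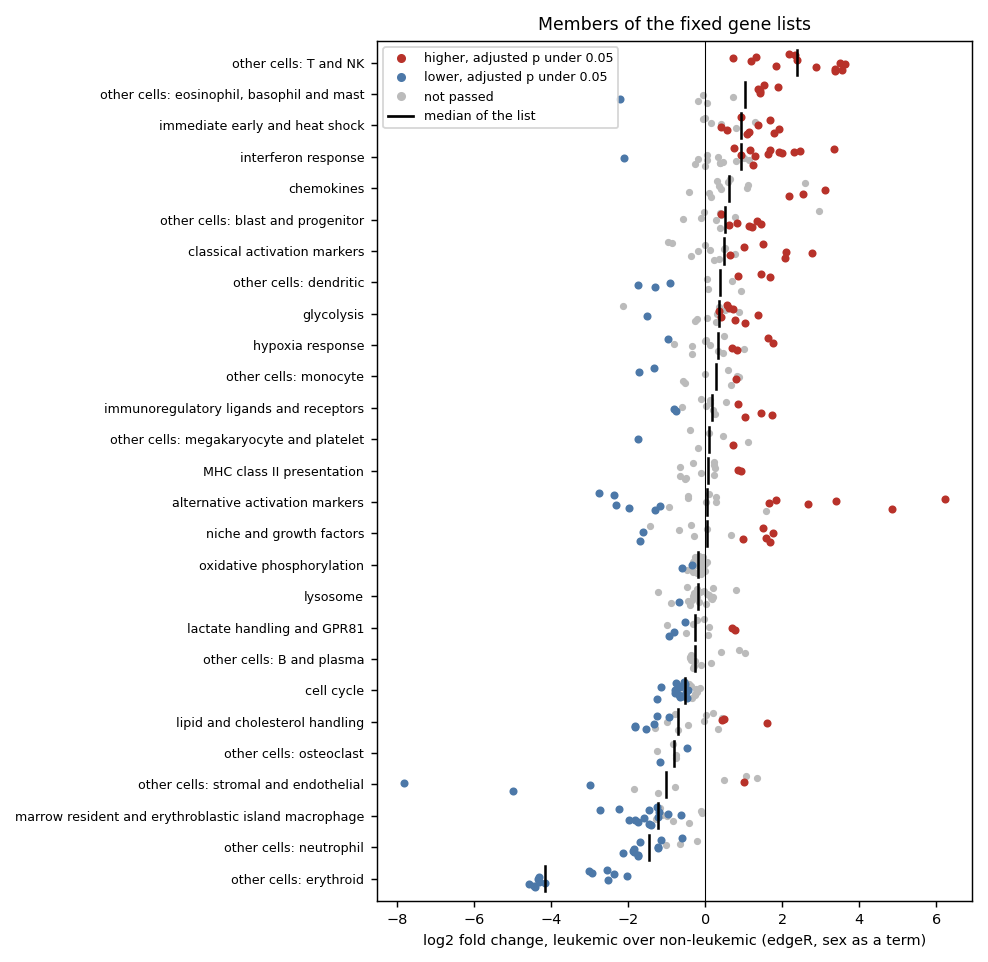
Each point is the log2 fold change (leukemic over non-leukemic, edgeR) of a tested member of a fixed gene list. Red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, and the black bar is the median of the list. Erythroid genes lie lowest, with a median of -4.16, and T and NK genes highest, with a median of 2.39.

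The erythroid genes held 2.34% ± 0.357 (SD, n = 6) of counts in non-leukemic and 0.23% ± 0.0623 in leukemic libraries, with an exact permutation p of 0.00216. All 13 also fell when adjusted over the list alone. Hbb-bs, a beta globin gene, went from 6988 ± 1241 to 306 ± 115 CPM, a log2 fold change of -4.57 ± 0.28 (SE, adjusted p = 9.47e-07). Alas2, the first enzyme of heme synthesis in red cells, fell by 4.31 ± 0.22 on the log2 scale (adjusted p = 4.08e-07), and Hbb-bt by 4.16 ± 0.28 (adjusted p = 1.88e-06). Reads of Hbb-bs and Hbb-bt, and of Hba-a1 and Hba-a2, are hard to assign between the near-identical copies. The list passed in camera (adjusted p = 8.67e-19) but not with an estimated correlation (adjusted p = 0.145 with an estimated correlation), and passed with fry (adjusted p = 1.55e-06). Among the 12 genes with the most negative fold changes under the naming rule were Sh3tc2, Redrum, Dmtn, Hbb-bs, Fhdc1, Ackr1, Hba-a2, Hba-a1 and Slc4a1, from -4.75 ± 0.45 for Sh3tc2 (82.3 ± 37.6 to 3.81 ± 3.06 CPM) to -4.32 ± 0.39 for Slc4a1. Dmtn and Slc4a1 encode parts of the red cell membrane and its skeleton, and Ackr1 is the Duffy antigen.

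T and NK genes went from 0.0496% ± 0.0110 (SD, n = 6) to 0.198% ± 0.0573 of counts, with an exact permutation p of 0.00216. Trac, a constant region of the T cell receptor, rose from 17.4 ± 7.88 to 218 ± 90.1 CPM, a log2 fold change of 3.64 ± 0.36 (SE, adjusted p = 3.43e-05). The T cell receptor gene Trbc2 rose by 3.51 ± 0.36 (adjusted p = 4.19e-05), Cd3g by 3.37 ± 0.34 (adjusted p = 3.67e-05), and Cd8a, the co-receptor of cytotoxic T cells, by 2.86 ± 0.28 (adjusted p = 3.10e-05). Ncr1, a receptor of NK cells, rose by 1.31. All 13 also rose when adjusted over the list alone. The camera test passed (adjusted p = 2.61e-13), while adjusted p = 0.220 with an estimated correlation. Of the 12 genes named for the largest positive fold changes, Gzmk, Tnfrsf4, Pdcd1, Cd5, Trgc1, Trac, Cd6 and Cd3e are known from lymphocytes, and rose by 5.35 ± 0.83 (Gzmk) to 3.56 ± 0.38 (Cd3e). Pdcd1, which encodes the checkpoint receptor PD-1, went from 4.61 ± 2.79 to 100.1 ± 47.2 CPM. Reads of T cell receptor segments such as Trgc1 may be shared among copies.

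The other 4 of these 12 genes were Gcg, Apoa1, Tph1 and Ccl24. Gcg, which encodes proglucagon, had 3 counts in all non-leukemic libraries together and 22187 in the leukemic libraries, a ratio of 5964 (95% counting interval 2040.5 to 28922) after scaling for depth, and reached 136 ± 82.3 CPM (SD, n = 6; adjusted p = 3.27e-07). Apoa1, the main protein of high-density lipoprotein, had 3 against 6901 counts, a ratio of 1855 (634 to 8997), with 43.4 ± 36.0 CPM in leukemic libraries (adjusted p = 3.16e-05). Tph1, the enzyme that starts serotonin synthesis outside the brain, had 10 counts, all in female non-leukemic replicate 2, against 6321, and reached 38.7 ± 31.4 CPM (adjusted p = 0.000232). Ccl24, a chemokine that attracts eosinophils, rose from 0.532 ± 0.343 to 38.9 ± 40.0 CPM, a log2 fold change of 6.23 ± 0.84 (adjusted p = 0.000296). With limma-voom, Apoa1 (adjusted p = 0.0543) and Tph1 (adjusted p = 0.132) did not pass.

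Markers of marrow resident and erythroblastic island macrophages, the cells that surround maturing red cells and recycle iron, fell in 14 of 22 tested genes, with 0 rising. Adjusted over the list alone, 18 fell. Slc40a1, the iron exporter ferroportin, went from 271 ± 26.1 to 72.2 ± 13.5 CPM (SD, n = 6), a log2 fold change of -1.99 ± 0.12 (adjusted p = 7.49e-07). Fcna fell by 2.73 ± 0.27 (adjusted p = 3.16e-05), Hpgd, which breaks down prostaglandins, by 2.22 ± 0.32 (adjusted p = 0.000476), and Hmox1, the heme-degrading enzyme, by 1.81 ± 0.28 (adjusted p = 0.000756). The adhesion molecule Vcam1 fell by 1.4 and the sialic acid receptor Siglec1 by 1.46. Their summed share went from 0.261% ± 0.136 to 0.111% ± 0.0211, with an exact permutation p of 0.00216. The list passed in camera (adjusted p = 6.34e-09), with adjusted p = 0.291 with an estimated correlation. Among the non-leukemic libraries the share was 0.535% in male replicate 3 and 0.180% to 0.239% in the others, and without that library 12 members fell. The gate genes moved apart: Adgre1 went from 121 ± 68.1 to 52.8 ± 12.3 CPM, a fall of 1.25 ± 0.30 on the log2 scale (adjusted p = 0.0129), and Ptprc, the gene of CD45, rose by 0.64 ± 0.18 (adjusted p = 0.0238). Without male non-leukemic replicate 1 or 2, Ptprc no longer passed (adjusted p = 0.0503 and 0.0543). Against a minimum change of 1.5-fold neither Adgre1 (adjusted p = 0.0914) nor Ptprc (adjusted p = 0.759) passed.

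**Figure D3:**
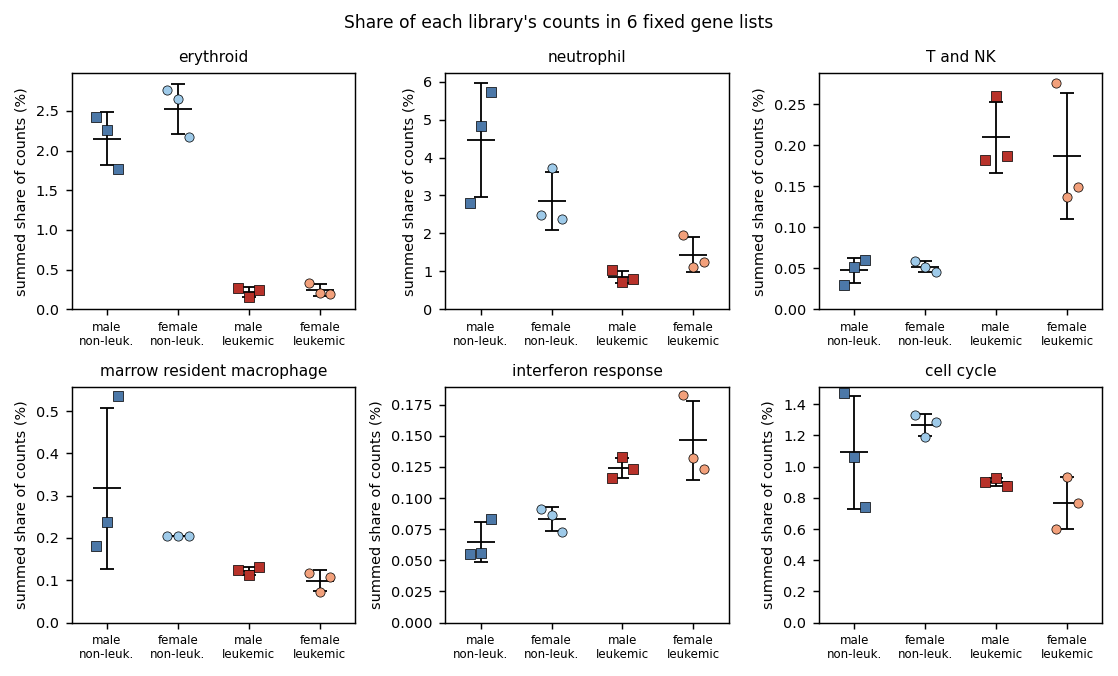
Each point is the share of a library's counts, in percent, in the genes of a fixed list, for 6 lists. Bars are the mean and SD of the 3 libraries of a group. The erythroid share is 2.34% on average in non-leukemic and 0.23% in leukemic libraries, and male non-leukemic replicate 3 has 0.535% in the resident macrophage genes.

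Lipid genes moved both ways, with 3 of 19 tested rising and 6 falling, or 4 and 8 adjusted over the list alone. The fatty acid receptor Cd36 fell by 1.81 ± 0.19 on the log2 scale (SE, adjusted p = 4.01e-05), the lipase Lpl by 1.81 ± 0.25 (adjusted p = 0.000328) and Lpcat3 by 0.93 ± 0.15 (adjusted p = 0.000925), while the fatty acid binding protein gene Fabp5 rose by 1.61 ± 0.27 (adjusted p = 0.00145). Apoe, a lipid carrier of macrophages, fell by 1.53. Erythroid (2.34% to 0.23% of counts), neutrophil (3.66% to 1.15%) and T and NK genes (0.0496% to 0.198%) moved in the same libraries. Which cells carry the lipid transcripts is therefore not known. The lipid list did not pass (camera adjusted p = 0.0737), but did without male non-leukemic replicate 1 (adjusted p = 0.0385) or replicate 2 (adjusted p = 0.0346). The count of rising lipid genes was 1, not 3, without either of these libraries, and also without female non-leukemic replicate 2, any 1 of the male leukemic libraries, or female leukemic replicate 3. With fry the list passed (adjusted p = 0.0316). Of 22 lysosomal genes, 1 fell, Ctsb, with a log2 fold change of -0.69 ± 0.18 (adjusted p = 0.0192), and 0 passed adjusted over the list alone. Ctsd (-0.44), Lamp1 (-0.39) and Atp6v0d2 (-1.22) did not pass, and the camera adjusted p was 0.272. Without male leukemic replicate 2, 0 lysosomal genes passed, without female leukemic replicate 1, 3 fell, and without male non-leukemic replicate 3, 2 fell and 2 rose. Male non-leukemic replicate 3 had 0.939% of its counts in the lysosomal list, against 0.539% to 0.592% in the other non-leukemic libraries.

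Markers of alternative activation, the macrophage state driven by type 2 cytokines, moved in both directions: 6 of 20 rose and 6 fell, or 7 and 8 adjusted over the list alone. Ccl24 is described above, and Retnla, Ccl17, Il10, Ccl22 and Egr2 also rose. Cd209a fell by 2.76 ± 0.31 on the log2 scale (SE, adjusted p = 7.76e-05), the hemoglobin scavenger receptor Cd163 by 2.31 ± 0.26 (adjusted p = 7.62e-05), and the mannose receptor Mrc1 by 1.98 ± 0.26 (adjusted p = 0.000204), from 61.2 ± 27.1 to 16.7 ± 7.48 CPM (SD, n = 6). Stab1, Chil3 and Clec10a also fell. Arg1, which breaks down arginine, had a log2 fold change of 1.58 ± 0.64 (adjusted p = 0.110), and passed only with DESeq2 among the settings tried (adjusted p = 0.0331). The camera test leaned down (adjusted p = 0.887), while the median of the list was 0.05 and its mean 0.46. The summed share of the list went from 0.246% ± 0.0748 to 0.123% ± 0.0336 of counts (exact permutation p = 0.00433, adjusted p = 0.00899). Mrc1 was at 115 CPM in male non-leukemic replicate 3 and at 39.6 to 56.8 in the other non-leukemic libraries. The shares of T and NK (0.0496% to 0.198%), eosinophil, basophil and mast cell (0.747% to 1.79%) and neutrophil genes (3.66% to 1.15%) moved in the same libraries. The cells behind the changes in alternative activation genes are therefore not known.

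Markers of classical, inflammatory activation rose in 6 of 17 tested genes and fell in 0, with the same counts adjusted over the list alone. The T cell attractants Cxcl9 and Cxcl10 rose by 2.77 ± 0.40 (adjusted p = 0.000426) and 2.09 ± 0.42 (adjusted p = 0.00438), the cytokine Il6 by 2.08 ± 0.33 (adjusted p = 0.000960) and the chemokine Ccl5 by 1.49 ± 0.36 (adjusted p = 0.0125). Socs3 and Il12a also rose, whereas Il1b (0.36) and Tnf (-0.37) did not pass. Nos2, the inducible nitric oxide synthase, was too low to test, with 7 counts in non-leukemic and 22 in leukemic libraries. The list passed in camera (adjusted p = 0.0198), with adjusted p = 0.471 with an estimated correlation. It did not pass without female non-leukemic replicate 3 (adjusted p = 0.0678) or female leukemic replicate 1 (adjusted p = 0.0988), and without the latter 2 members fell. With fry it did not pass (adjusted p = 0.0507). T and NK genes, which rose in the same libraries, mark cells that also express Ccl5.

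Interferon response genes rose in 12 of 25 tested genes and fell in 1, or in 15 and 1 adjusted over the list alone. Iigp1, Gbp2, Gbp3 and Igtp, GTPases induced by interferon gamma, rose by 3.34 ± 0.21 (adjusted p = 9.47e-07), 2.30 ± 0.17 (adjusted p = 3.45e-06), 1.90 ± 0.17 (adjusted p = 1.36e-05) and 1.67 ± 0.16 (adjusted p = 2.94e-05). The antiviral gene Rsad2 fell by 2.11, and Isg15 had a log2 fold change of -0.00. Camera passed the interferon list (adjusted p = 1.23e-07), with adjusted p = 0.291 with an estimated correlation. Its summed share rose from 0.0741% to 0.135% of counts, and was highest in female leukemic replicate 1, at 0.183%. Chemokine genes rose in 3 of 14 and fell in 0, and the same 3 passed adjusted over the list alone. Ccl3, which draws monocytes and T cells, rose from 28.7 ± 8.17 to 133 ± 48.5 CPM (SD, n = 6), a log2 fold change of 2.2 ± 0.28 (adjusted p = 0.000202). Ccl4 rose by 2.54 ± 0.36 and Ccl8 by 3.10 ± 0.58, and Cxcl13 (2.59 ± 1.13, adjusted p = 0.139) did not pass. Genes of T and NK cells rose in the same libraries, from 0.0496% to 0.198% of counts, and the counts do not tell which cells carry the interferon and chemokine transcripts. The chemokine list passed in camera (adjusted p = 0.00210), with adjusted p = 0.379 with an estimated correlation, and 6 genes rose without male non-leukemic replicate 3.

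Immunoregulatory genes rose in 4 of 14 and fell in 2, with the same counts adjusted over the list alone. Cd274, which encodes the PD-1 ligand PD-L1, rose from 13.4 ± 3.83 to 28.9 ± 2.50 CPM (SD, n = 6), a log2 fold change of 1.05 ± 0.17 (adjusted p = 0.00101). Pdcd1lg2, the other PD-1 ligand, rose by 1.74 ± 0.29 (adjusted p = 0.00128), Cd200r1 by 0.85 ± 0.21 (adjusted p = 0.0128) and Havcr2 by 1.44 ± 0.35 (adjusted p = 0.0129). Vsir and Sirpa fell, but 0 members fell in the fits without female non-leukemic replicate 2, any 1 of the male leukemic libraries, or female leukemic replicate 2 or 3, and 1 fell without male non-leukemic replicate 1 or 2 or female non-leukemic replicate 1 or 3. The list did not pass (camera adjusted p = 0.115), but did without male non-leukemic replicate 3 (adjusted p = 0.0229). Niche and growth factor genes rose in 5 of 13 and fell in 2, with the same counts adjusted over the list alone. The macrophage growth factor Csf1 rose by 1.68 ± 0.22 (adjusted p = 0.000200), Tnfsf10 by 1.76 ± 0.22 (adjusted p = 0.000182) and Hgf by 1.5 ± 0.19 (adjusted p = 0.000192), while the B cell survival factor Tnfsf13b fell by 1.62 ± 0.24 (adjusted p = 0.000580). Spp1 and Osm also rose and Igf1 fell. T and NK genes (0.0496% to 0.198% of counts) and eosinophil, basophil and mast cell genes (0.747% to 1.79%) rose in the same libraries, and the counts do not tell which cells carry the immunoregulatory and niche transcripts. The niche list did not pass in camera (adjusted p = 0.272) and passed with fry (adjusted p = 0.00567). Genes of MHC class II presentation rose in 2 of 12, H2-Oa (0.86 ± 0.20, adjusted p = 0.0112) and H2-DMb2 (0.94 ± 0.30, adjusted p = 0.0472), as they did adjusted over the list alone. H2-Eb1 and Cd74 both had a log2 fold change of -0.66 and did not pass, and the camera adjusted p was 0.549. Without male non-leukemic replicate 3, which had 1.97% of its counts in this list against 0.529% to 0.754% in the other non-leukemic libraries, 4 members rose. In every other single-library omission but that of female leukemic replicate 2, 1 member rose, as with limma-voom and with replicate number as a block.

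The lactate receptor gene Hcar1 had 0 counts in all 12 libraries, which allows up to 0.1 to 0.177 CPM per library. Among the genes of lactate handling, 2 of 12 rose and 3 fell, with the same counts adjusted over the list alone. Ldha, a subunit of lactate dehydrogenase, rose from 1105 ± 95.1 to 1893 ± 207 CPM (SD, n = 6), a log2 fold change of 0.70 ± 0.11 (SE, adjusted p = 0.000953). The lactate transporter gene Slc16a1 (MCT1) fell from 394 ± 100.1 to 216 ± 48.5 CPM, by 0.95 ± 0.18 on the log2 scale (adjusted p = 0.00314). Bsg, the chaperone of this transporter, fell by 0.80 ± 0.13 (adjusted p = 0.00124), and Emb, a related chaperone, rose by 0.78 ± 0.17 (adjusted p = 0.00620). Erythroid genes fell in the same libraries, from 2.34% to 0.23% of counts, and the counts do not tell which cells carry the transcripts of Slc16a1, Bsg and the other lactate genes. Slc16a3 (MCT4) differed by less than its error, with a log2 fold change of 0.07 ± 0.18 (adjusted p = 0.838). The lactate list did not pass in camera (adjusted p = 0.563; 0.669 with an estimated correlation), but passed with fry (adjusted p = 0.0316), with a median of -0.26. Its summed share of counts rose from 0.274% to 0.320% (exact permutation p = 0.00216, adjusted p = 0.00584), so members and sum point in different directions. Neither Ldha (adjusted p = 0.394) nor Slc16a1 (adjusted p = 0.111) passed against a minimum change of 1.5-fold.

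**Figure D4:**
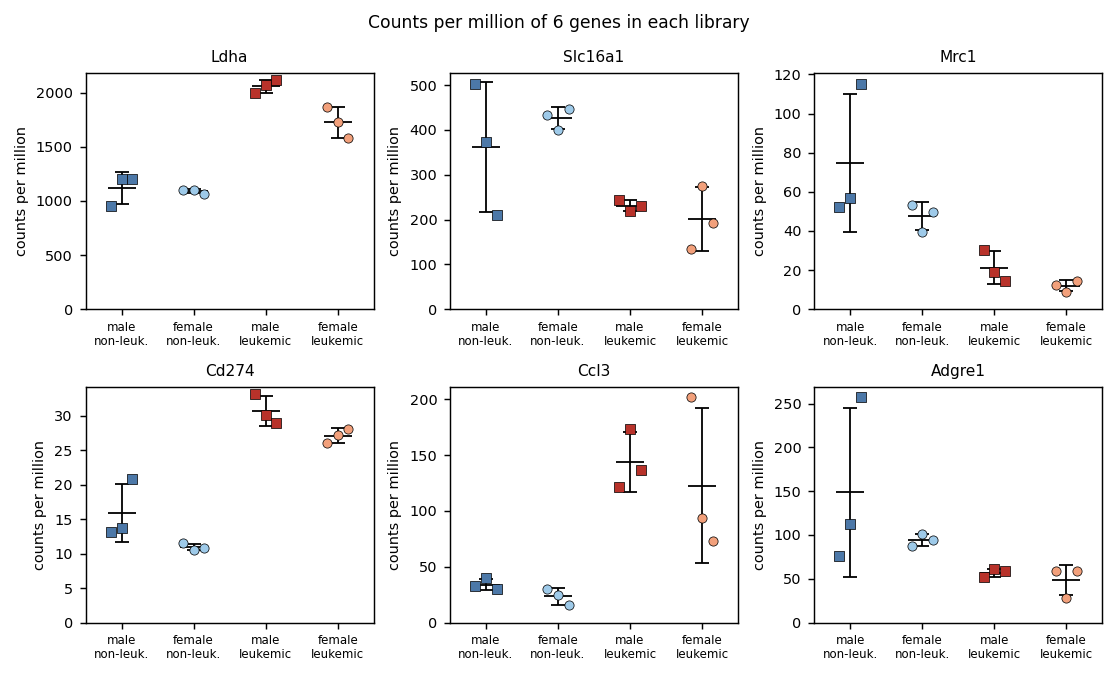
Each point is the CPM of a gene in a library, for Ldha, Slc16a1, Mrc1, Cd274, Ccl3 and Adgre1. Bars are the mean and SD of the 3 libraries of a group. Ldha averages 1105 CPM in the 6 non-leukemic and 1893 CPM in the 6 leukemic libraries, and Mrc1 61.2 and 16.7 CPM.

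Glycolysis genes rose in 8 of 19 and fell in 1, or in 10 and 1 adjusted over the list alone. Pfkp, a phosphofructokinase, rose by 1.37 ± 0.19 (adjusted p = 0.000310), Pgk1 by 0.72 ± 0.11 (adjusted p = 0.000710) and the glucose transporter gene Slc2a1 by 1.04 ± 0.23 (adjusted p = 0.00693), while Pfkm, the muscle phosphofructokinase, fell by 1.51 ± 0.28 (adjusted p = 0.00237). By camera the glycolysis list passed (adjusted p = 0.00116), with adjusted p = 0.379 with an estimated correlation. The count of rising genes was 4 without male non-leukemic replicate 2, 13 without male non-leukemic replicate 3, and 5 without any 1 of the female non-leukemic libraries. The shares of erythroid (2.34% to 0.23%), neutrophil (3.66% to 1.15%) and T and NK genes (0.0496% to 0.198%) moved in the same libraries, so the cells behind the changes in glycolysis, oxidative phosphorylation and hypoxia genes are not known. Oxidative phosphorylation genes fell in 2 of 28, Ndufv1 (-0.61 ± 0.12, adjusted p = 0.00378) and Uqcrc1 (-0.35 ± 0.10, adjusted p = 0.0287), and in 1 adjusted over the list alone. Ndufs1 (-0.48) and Cox4i1 (-0.31) did not pass. The list passed in camera (adjusted p = 0.0104), with adjusted p = 0.631 with an estimated correlation, and did not pass without female leukemic replicate 2 (adjusted p = 0.0677) or replicate 3 (adjusted p = 0.117). It did not pass with fry (adjusted p = 0.154). Without female leukemic replicate 1, 17 of its genes fell, and without male non-leukemic replicate 3, 4 fell. In every other single-library omission but that of male non-leukemic replicate 2, 1 fell. Of the hypoxia response genes, 4 of 15 rose and 1 fell, with the same counts adjusted over the list alone. Bhlhe40 rose by 1.62 ± 0.24 (adjusted p = 0.000506), Ddit4 by 1.76 ± 0.39 (adjusted p = 0.00701) and Ndrg1 by 0.69 ± 0.15 (adjusted p = 0.00580), Mxi1 fell by 0.96 ± 0.11 (adjusted p = 0.000114), and the list did not pass in camera (adjusted p = 0.0793) but passed with fry (adjusted p = 0.00207).

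Cell cycle genes fell in 16 of 25 and rose in 0, and 18 fell adjusted over the list alone. Rrm2, which makes nucleotides for DNA synthesis, fell by 1.16 ± 0.18 (adjusted p = 0.000653), the mitotic kinase gene Aurka by 0.78 ± 0.13 (adjusted p = 0.000964), Birc5 by 0.75 ± 0.14 (adjusted p = 0.00267) and the proliferation marker Mki67 by 1.25 ± 0.24 (adjusted p = 0.00280). The list passed in camera (adjusted p = 1.09e-07), with adjusted p = 0.379 with an estimated correlation, and 10 genes fell without male non-leukemic replicate 1. Erythroid genes fell in the same libraries, as given above. Immediate early and heat shock genes, which respond within minutes to stress or handling, rose in 9 of 15 and in 10 adjusted over the list alone. Egr1 rose by 1.91 ± 0.17 (adjusted p = 1.79e-05), Fos by 1.08 ± 0.15 (adjusted p = 0.000355), Ier3 by 1.38 ± 0.21 (adjusted p = 0.000678) and Fosb by 1.78 ± 0.32 (adjusted p = 0.00216). The camera test passed (adjusted p = 6.22e-06), with adjusted p = 0.220 with an estimated correlation. Blast and progenitor genes rose in 7 of 16 and in 9 adjusted over the list alone. Hoxa9 rose by 1.45 ± 0.20 (adjusted p = 0.000314), Gata2 by 1.35 ± 0.20 (adjusted p = 0.000531), Flt3 by 1.15 ± 0.19 (adjusted p = 0.00124) and Cd34, a marker of progenitors, by 1.21 ± 0.21 (adjusted p = 0.00151). This list passed in camera (adjusted p = 7.51e-05), with adjusted p = 0.291 with an estimated correlation, and 11 of its genes rose without the 2 libraries standing apart. The summed share of the blast list was 0.863% ± 0.274 (SD, n = 6) without and 1.08% ± 0.217 with leukemia (exact permutation p = 0.128, adjusted p = 0.172), and at 1.34% male non-leukemic replicate 3 lay above all leukemic libraries but female replicate 2 (1.42%).

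Neutrophil genes fell in 11 of 14 and in 12 adjusted over the list alone, and their share went from 3.66% ± 1.38 (SD, n = 6) to 1.15% ± 0.442 of counts. The granule protein genes Ltf (-1.88 ± 0.23, adjusted p = 0.000158), Camp (-1.85 ± 0.35, adjusted p = 0.00281) and Ngp (-1.85 ± 0.35, adjusted p = 0.00296) fell, as did the gate gene Ly6g (-2.12 ± 0.43, adjusted p = 0.00445). The neutrophil list passed in camera (adjusted p = 7.29e-07), with adjusted p = 0.379 with an estimated correlation. Eosinophil, basophil and mast cell genes rose in 5 of 10 and fell in 1, or in 6 and 1 adjusted over the list alone. The IgE receptor genes Fcer1a (1.90 ± 0.28, adjusted p = 0.000538) and Ms4a2 (1.37 ± 0.25, adjusted p = 0.00226) and the basophil protease gene Prss34 (1.52 ± 0.23, adjusted p = 0.000587) rose, and Ccr3, a chemokine receptor of eosinophils, fell by 2.22 ± 0.27 (adjusted p = 0.000152). This list passed in camera (adjusted p = 0.0267), with adjusted p = 0.528 with an estimated correlation, and did not pass without female non-leukemic replicate 1 (adjusted p = 0.0617) or replicate 3 (adjusted p = 0.0537) or female leukemic replicate 1 (adjusted p = 0.0605), nor with fry (adjusted p = 0.0521). Of 10 monocyte genes, 1 rose and 2 fell, Fcnb and Cx3cr1, or 2 rose and 3 fell adjusted over the list alone, with a camera adjusted p of 0.962, a median of 0.28 and a mean of -0.04. Without male non-leukemic replicate 2 and without replicate 3, 2 and 3 monocyte genes rose. The gate gene Ly6c2 had a log2 fold change of -0.52 ± 0.37 (adjusted p = 0.379), and passed without female leukemic replicate 1 (-0.85, adjusted p = 0.0313), which had 410 CPM of it against 121 to 198 in the other leukemic libraries. Ly6c1, whose reads are hard to tell from those of Ly6c2, had 0.68 ± 0.65 (adjusted p = 0.540).

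The remaining lists of other cells did not pass in camera. Of 12 B and plasma cell genes 0 passed, also adjusted over the list alone, with Jchain at 1.03 ± 0.56 (adjusted p = 0.245), Ighm at 0.88 ± 0.49 (adjusted p = 0.251), Pax5 at -0.36 and Igll1 at -0.39, and a camera adjusted p of 0.549. Of 7 megakaryocyte genes Itga2b rose (0.72 ± 0.21) and Gp9 fell (-1.74 ± 0.28), with the same counts adjusted over the list alone and a camera adjusted p of 0.793. No megakaryocyte gene rose in the fits without male non-leukemic replicate 1 or 2, any 1 of the female non-leukemic libraries, male leukemic replicate 3, or female leukemic replicate 2 or 3, and 2 rose without male leukemic replicate 2. Dendritic cell genes rose in 3 of 10 and fell in 3, also adjusted over the list alone, with Cd7 (1.69 ± 0.25) and Ccr7 (0.86 ± 0.18) higher, Zbtb46 (-1.75 ± 0.31) and Siglech (-1.30 ± 0.23) lower, and a camera adjusted p of 0.458. T and NK genes rose in the same libraries (0.0496% to 0.198% of counts), and the counts do not tell which cells carry Cd7 and Ccr7. Of 10 stromal and endothelial genes 1 rose and 3 fell, or 2 and 5 adjusted over the list alone, with a camera adjusted p of 0.257. Pecam1 rose by 1.00 ± 0.18, the collagen gene Col1a1 fell by 4.98 ± 1.04 and Sparc by 2.98 ± 0.68. Bglap, which encodes osteocalcin, had 463 counts in non-leukemic and 2 in leukemic libraries, a ratio of 287 (95% counting interval 79.0 to 2378). Col1a1 was at 150 CPM in male non-leukemic replicate 2, 332 in replicate 3 and 10.4 to 29.0 in the other non-leukemic libraries, and Bglap at 5.26, 12.4 and 0.263 to 1.63 CPM. The summed share of the stromal list was 0.0365% and 0.0723% in these replicates, 0.00939% to 0.0125% in the other non-leukemic and 0.00735% to 0.0194% in the leukemic libraries (exact permutation p = 0.703), and 2 stromal genes rose without male non-leukemic replicate 2. Of 6 osteoclast genes, Acp5 (-1.16 ± 0.18) and Atp6v0d1 (-0.48 ± 0.14) fell, also adjusted over the list alone, with a camera adjusted p of 0.0559. That list passed without male non-leukemic replicate 1 (adjusted p = 0.0329) or male leukemic replicate 2 (adjusted p = 0.0427). It passed with fry (adjusted p = 0.0220), and its summed share fell from 0.0378% to 0.0231% (exact permutation p = 0.00216, adjusted p = 0.00584). In single-library omissions 1 osteoclast gene fell, except without male non-leukemic replicate 3, female non-leukemic replicate 3 or female leukemic replicate 1.

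Of the 27 lists, 13 passed in camera, 8 higher and 5 lower. With an estimated correlation 0 passed in limma camera, where 3 had an unadjusted p under 0.05, and 15 passed with fry. The lists of fry are not all those of camera: oxidative phosphorylation, classical activation and the eosinophil list were lost, and the lactate, hypoxia, lipid, niche and osteoclast lists were added. The exact permutation test of summed shares passed for 16 lists.

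Within each sex the leukemic effect was tested in a model of all 4 groups. In males 1162 genes passed with edgeR, 526 higher and 636 lower in leukemic libraries, and in females 1328 passed, 605 higher and 723 lower. In fits of only the libraries compared, the balance turned in males, with 703 higher and 554 lower of 1257 (55.9% higher against 45.3%), and females had 364 higher and 578 lower of 942. Lymphocyte and interferon genes led the rises in males, with the T cell adaptor gene Lat at 2.52 ± 0.18 (SE, n = 3 per group), Eomes, a factor of cytotoxic lymphocytes, at 3.28 ± 0.27, Gbp2 at 2.58 ± 0.22, Gbp3 at 2.26 ± 0.19 and the T cell factor Tcf7 at 2.47 ± 0.21, each with an adjusted p of 7.21e-05. Genes of heme and red cells were among the leading falls in males, with Alas2 at -4.36 ± 0.33, Bpgm at -3.20 ± 0.26 and the mitochondrial iron importer Slc25a37 at -2.63 ± 0.22, each with an adjusted p of 7.21e-05. The ganglioside enzyme gene St3gal5 also fell in males (-2.57 ± 0.21, adjusted p = 7.21e-05). In females Lat rose by 2.41 ± 0.18 (adjusted p = 6.94e-05), Iigp1 by 3.37 ± 0.31 (adjusted p = 0.000150), the granzyme gene Gzmb by 3.35 ± 0.34 (adjusted p = 0.000281) and Gbp2 by 2.01 ± 0.21 (adjusted p = 0.000337), and Gcg was also among the rises (adjusted p = 0.000148). The falls in females were led by St3gal5 (-2.87 ± 0.21), Slc25a37 (-2.86 ± 0.22), Alas2 (-4.26 ± 0.33), Smox (-2.67 ± 0.21) and Mkrn1 (-1.74 ± 0.13), each with an adjusted p of 6.94e-05.

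Rising genes of both sexes shared 285 calls, where independent lists give 20.2, and falling genes shared 381, where they give 29.2, and 0 genes passed in opposite directions. Of the 2822 genes of the pooled comparison, 2821 had the same sign in both sexes. These genes were chosen by an effect pooled over the same libraries, which favours equal signs, so this count is no separate evidence. Across 8308 genes, which are not independent replicates, the fold changes of the sexes correlated with r = 0.75 and rho = 0.60. Among the genes named at the start, Slc16a1 had -0.78 in males (adjusted p = 0.0931) and -1.11 in females (adjusted p = 0.0222), Cd274 had 0.78 (adjusted p = 0.0532) and 1.31 (adjusted p = 0.00483), and Adgre1 had -1.57 (adjusted p = 0.0465) and -0.93 (adjusted p = 0.209); the difference between the sexes did not pass for any of these, with interaction adjusted p of 0.876, 0.824 and 0.845. The count in males was 732 without male non-leukemic replicate 2, 604, 513 and 536 without male leukemic replicates 1, 2 and 3, and 2087 without female leukemic replicate 1. The count in females was 504, 682 and 710 without female non-leukemic replicates 1, 2 and 3.

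A difference of the leukemic effect between the sexes was tested as an interaction. Chance alone puts 0.05 of the 15758 genes tested under an unadjusted p of 0.05. With edgeR 0 of 15758 genes passed, with 925, somewhat more than chance gives, at an unadjusted p under 0.05 and a smallest adjusted p of 0.797, limma-voom gave 0, and DESeq2 gave 23, with 10 higher and 13 lower in females. Those with the lowest p in DESeq2 were Sostdc1 (-21.3 on the log2 scale), Dpysl3 (21.3), Rgs16 (-5.91), Camk4 (-4.04) and the immunoglobulin segment Igkv8-16 (7.10), named after their values were seen. Among gene lists, camera with its preset correlation passed 11 of 27, 7 toward higher and 4 toward lower values in females, while 0 passed with an estimated correlation (limma camera, 1 at an unadjusted p under 0.05) and 0 with fry (2 at an unadjusted p under 0.05). The neutrophil list had the lowest camera p, with medians of -2.13 in males and -0.75 in females (adjusted p = 2.31e-11; adjusted p = 0.331 with an estimated correlation, 0.336 with fry). Eosinophil, basophil and mast cell genes had medians of 0.51 in males and 1.47 in females (adjusted p = 0.000169; adjusted p = 0.331 with an estimated correlation), B and plasma cell genes -0.67 and 0.24 (adjusted p = 0.00191; adjusted p = 0.331 with an estimated correlation), and T and NK genes 2.71 and 2.47 (adjusted p = 0.00192; adjusted p = 0.698 with an estimated correlation). The share of B and plasma cell genes was 4.54% and 3.35% in female leukemic replicates 1 and 3, 0.502% in replicate 2 and 0.306% to 0.565% in the male leukemic libraries. The T and NK list did not pass without male non-leukemic replicate 1 (adjusted p = 0.0708), female leukemic replicate 2 (adjusted p = 0.0509) or replicate 3 (adjusted p = 0.0646).

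Females and males were compared within each condition, where genes of the sex chromosomes check the labels. In non-leukemic libraries Xist, the RNA that silences an X chromosome, had a log2 difference of 5.58 (female minus male), and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had -7.07, -11.89, -11.24 and -7.67. In leukemic libraries the differences were 5.17 for Xist and -5.04, -4.16, -3.06 and -4.25 for the same Y-linked genes. The female leukemic libraries held traces of Y-linked genes, summing to 1.42 to 14.9 CPM against 102 to 183 in males, and their origin was not tested. Each difference lay on the side its label calls for, but none passed in edgeR, with adjusted p of 0.212 (Eif2s3y) to 0.599 (Xist, Uty) without leukemia and 0.382 (Xist, Eif2s3y) to 0.5 (Kdm5d) with it. These large differences were missed although edgeR recovered 82% and 80% of 4-fold changes in the simulation. A count of 0 in these comparisons therefore does not show that the sexes are alike. In the non-leukemic comparison edgeR passed 0 genes, with 769 at an unadjusted p under 0.05 and a smallest adjusted p of 0.212, limma-voom passed 0, and DESeq2 passed 34, among them Kdm5d (adjusted p = 1.95e-05), Eif2s3y (adjusted p = 3.94e-05), Uty (adjusted p = 0.000357), Ddx3y (adjusted p = 0.0177) and Socs3 (-2.48, adjusted p = 3.15e-06). Chance alone puts 0.05 of the 15758 genes tested under that unadjusted p, which the 769 do not exceed. The DESeq2 calls with the lowest p in this comparison were Sostdc1 (21.6, adjusted p = 1.26e-14) and Dpysl3 (-19.5, adjusted p = 5.26e-10), named after their values were seen. Both differences are larger in size than those of the Y-linked genes, and edgeR passed neither gene. In the leukemic comparison edgeR passed 0 genes, with 1370, more than chance gives, at an unadjusted p under 0.05 and a smallest adjusted p of 0.382, limma-voom passed 0, and DESeq2 passed 120, with 87 higher and 33 lower in females. The DESeq2 calls with the lowest p were Ighv1-85 (3.47), Igkv3-2 (3.02), Gp5 (1.05) and Pf4 (1.88), and Fcer1a (1.88) also passed. The Y-linked genes did not pass in DESeq2 in leukemic libraries, with adjusted p of 0.0922 (Eif2s3y), 0.130 (Ddx3y), 0.334 (Uty) and 0.366 (Kdm5d). Xist had no adjusted p in DESeq2 in either comparison. The DESeq2 calls in leukemic libraries thus include none of the genes that check the labels. Reads of immunoglobulin segments are hard to assign among copies. In single-library omissions with edgeR, Xist passed in both comparisons without male leukemic replicate 1 (adjusted p = 0.0235 without and 0.00997 with leukemia) and Uty in both without female leukemic replicate 3 (adjusted p = 0.00584 and 0.0267). Without female leukemic replicate 2, Kdm5d, Eif2s3y and Socs3 passed in non-leukemic libraries (adjusted p = 0.0115, 0.0357 and 0.0357), and Igkv10-94, Ighm and Mzb1 in leukemic libraries (adjusted p = 0.0176, 0.0255 and 0.0255). Sowaha, like the last 3 genes named after its values were seen, passed in the leukemic comparison without female leukemic replicate 1 (-2.97, adjusted p = 0.0217) and without both libraries standing apart (-2.97, adjusted p = 0.0433).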

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

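For the first pattern below all 4 tests were chosen after the results were seen, and the other tests were written before. Within a condition, 26 of 128 tests of a lowest or highest library found a gap to its nearest neighbour that was large for the range of the 6 libraries, where chance gives 6.40.

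Male non-leukemic replicate 3 was set apart from the other non-leukemic libraries in 13 of the tests with a large gap. Its gap was 0.801 of the range for Adgre1, 0.772 for Mrc1 (115 CPM against 39.6 to 56.8), 0.687 for Cd274 (20.8 CPM against 10.6 to 13.8) and 0.632 for Slc16a3 (79.2 CPM against 33.4 to 50.3). In share of counts its gap was 0.866 for lysosomal genes, 0.843 for MHC class II genes, 0.835 for resident macrophage genes, 0.782 for lipid genes (0.531% against 0.231% to 0.296%), 0.710 for immunoregulatory genes, 0.702 for chemokines, 0.656 for glycolysis and 0.644 for classical activation, all on the high side. Lactate genes were lowest in this library, at 0.249% against 0.276% to 0.283%, a gap of 0.801.

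Female leukemic replicate 1 had the highest Ly6c2 (gap 0.734), the highest shares of interferon genes (0.756; 0.183% against 0.116% to 0.133%) and monocyte genes (0.729; 0.317% against 0.187% to 0.222%), and the lowest share of stromal genes (0.737; 0.00735% against 0.0162% to 0.0194%). This library had the highest total counts, yet no count for 4.42% of genes that averaged 2 to 20 CPM in the other libraries. In each of the others this was 0.120% to 0.842%. Whether library quality lies behind its extreme values was not tested. Female leukemic replicate 2 had the lowest Adgre1 (0.729; 28.4 CPM against 51.8 to 60.6) and the highest share of eosinophil, basophil and mast cell genes (0.717; 3.58% against 1.10% to 1.80%). Gzmk (0.892; 5.31 CPM against 0.177 to 0.731) and Cd3e (0.695; 16.1 CPM against 5.03 to 8.42) were highest in female non-leukemic replicate 1, and among leukemic libraries Gzmk was highest in male replicate 2 (0.666; 103 CPM against 22 to 48.9). Ly6c1 was highest in male leukemic replicate 3 (0.643; 1.55 CPM against 0.0666 to 0.595) and Nos2 in male leukemic replicate 1 (0.850; 0.665 CPM against 0 to 0.1). With a gap of 1, Tph1 (0.499 CPM) was counted only in female replicate 2 and Nos2 (0.414 CPM) only in male replicate 2 among the non-leukemic libraries.

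With a preset correlation, camera passed a difference of the leukemic effect between the sexes for 11 lists, but with an estimated correlation each had an adjusted p of at least 0.331, fry passed 0 (2 at an unadjusted p under 0.05), and another split of the libraries gave 19. Besides the neutrophil (adjusted p = 2.31e-11), eosinophil (0.000169), B cell (0.00191) and T and NK (0.00192) lists of the report, these were immunoregulatory genes (median -0.08 in males and 0.64 in females, adjusted p = 0.00192), cell cycle genes (-0.47 and -0.65, 0.00191), blast genes (0.39 and 0.80, 0.00373), monocyte genes (-0.22 and 0.24, 0.00540), megakaryocyte genes (-0.22 and 0.55, 0.0348), dendritic cell genes (0.67 and 0.18, 0.0385) and osteoclast genes (-0.32 and -1.28, 0.0395). Without male non-leukemic replicate 3 the immunoregulatory (0.115), cell cycle (0.256) and monocyte (0.168) lists did not pass, and without female leukemic replicate 2 the T and NK (0.0509), megakaryocyte (0.115), dendritic (0.202) and osteoclast (0.115) lists did not. The megakaryocyte list also failed without male non-leukemic replicate 1, female non-leukemic replicate 2, male leukemic replicate 2 or female leukemic replicate 3 (0.0639 to 0.108). The dendritic list failed without male non-leukemic replicate 1 or 2, female non-leukemic replicate 1, male leukemic replicate 1 or female leukemic replicate 3 (0.0516 to 0.130), and the osteoclast list without male non-leukemic replicate 1, female non-leukemic replicate 3, male leukemic replicate 1 or 3 or female leukemic replicate 1 (0.0516 to 0.0886). Other lists newly passed when 1 library was left out. MHC class II genes did without male non-leukemic replicate 1 or 2 or female leukemic replicate 2 (0.00803 to 0.0372). Lysosomal genes did without male non-leukemic replicate 1 (0.0168) or 2 (0.0347). Oxidative phosphorylation did without female leukemic replicate 3 (0.0129) and chemokines without male leukemic replicate 3 (0.0387). Interferon (0.0362) and erythroid genes (0.0479) did without female leukemic replicate 1. With the strict low-count filter the megakaryocyte (0.0520), dendritic (0.109) and osteoclast (0.514) lists were lost and chemokines (0.00774) passed. Without both libraries standing apart, a fit added after seeing the data, the immunoregulatory (0.209), cell cycle (0.530) and monocyte (0.248) lists were lost, and interferon (2.65e-05) and alternative activation genes (0.0157) passed in the same direction as with all libraries.

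The first pattern weighed is the fall of erythroid and rise of T and NK genes. A lower share of the main cell type would raise the markers of all other cells alike only if those cells kept their proportions to each other. Among 7 other blood cell lists, without the erythroid and T and NK lists, the medians ran from -1.46 (neutrophil) to 1.05 (eosinophil, basophil and mast). This argues against a lower share of the main cell type alone. A lower share together with shifts among the other cells cannot be judged from these medians. The gap in erythroid share allows a shift of all other genes by only 0.0308 on the log2 scale. This argues against the loss of erythroid counts alone as the source of the T and NK rise. Other abundant genes were not part of that test, so it cannot judge whether they took up counts. A second erythroid list, without genes of the first, fell in 96.3% of 27 genes (median -2.74), and a second T cell list rose in 86.4% of 22 (median 2.46). Fewer erythroid cells or fragments and more T cells in the sorted material, at Hbb-bs levels of 6988 and 306 CPM and Trac levels of 17.4 and 218 CPM, may therefore explain the pattern, although a gate on CD45 and F4/80 would be meant to remove them, and a change in the macrophages' own or ingested RNA stays open.

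The second pattern is the fall of resident macrophage genes. A single library as the cause is argued against, as 12 of 22 genes fell without male non-leukemic replicate 3 (median -0.95). A lower share of macrophages in the sorted cells could not be settled: a second macrophage list had a median of -0.46, with 3 of 17 genes falling. Adgre1, the gated antigen's gene, fell as well. A change within the macrophages in leukemia, or a loss of 1 kind of macrophage, may explain it equally and was not tested.

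The third pattern is Gcg and Apoa1, seen almost only in leukemic libraries. RNA of islet, gut or liver cells as a group is argued against. The 19 abundant genes of such cells summed to 0.0171 of the CPM of Gcg (2.32 CPM). Many of them, such as Ins1 and Alb, had 0 CPM in every library. However, Pyy was counted only in leukemic libraries, and Chga had a log2 fold change of 2.82 (adjusted p = 0.129). RNA of a single kind of gut cell therefore stays open. The CD45 gate does not decide this, since stromal genes such as Col1a1 were counted in spite of it. Activation of the chromosome region stays open, with 20% of the 20 nearest tested genes rising (Slc4a10 and Dpp4 near Gcg, Sik3 and Bud13 near Apoa1, order from GRCm38.p6), against 1373 of 15758 genes tested in all. Others of the 20 fell past the threshold: Gca near Gcg (-0.97), and Nxpe4 (-1.68) and Nxpe2 (-3.34) near Apoa1. Genes too low to test are not among the 20, such as Apoa4 of the Apoa1 cluster, with 0 counts in all 12 libraries. Expression by the leukemic cells or the macrophages in leukemia may explain the pattern and was not tested.

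Other splits of the libraries argue against chance for the main count of genes (2822, highest other split 502). Of 100 splits drawn from 462, only the real one gave as many. The splits treat libraries as independent, which the labels do not tell, and cannot separate leukemia from another difference between the conditions. They do not argue against chance for the gene lists (13, highest other 15, with 9 of 100 splits giving as many) or the interaction lists (11, highest other 19, with 34 of 100). A real count of 0 is matched by every split, so the splits decide nothing for the interaction genes (0 with edgeR, highest other 1, 925 at an unadjusted p under 0.05, 0 with limma-voom and 23 with DESeq2) or for the sex comparisons (0 and 0 with edgeR, highest other 0 and 0, in 10 splits, 769 and 1370 at an unadjusted p under 0.05, 0 and 0 with limma-voom and 34 and 120 with DESeq2). Chance alone puts 0.05 of the 15758 genes under an unadjusted p of 0.05, which 925 and 1370 exceed and 769 does not. For males (1162, highest other 0) and females (1328, highest other 1), the 10 splits are too few for a share under 0.05.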

How the results depend on the processing

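The fit without female leukemic replicate 1 and male non-leukemic replicate 3 was chosen after seeing the data, and the other alternatives before. Of 972 list results under alternatives, 871 kept their side of the threshold, 74 no longer passed, 22 newly passed and 5 reversed direction. A change of direction was counted only where the main fit or the alternative passed. Single genes were followed only if named for the largest fold changes or named whatever their values, without the sex genes. Of their 755 results, 744 kept their side of the threshold, 8 no longer passed and 3 newly passed. Genes named only as list members or for other comparisons are not in this count. Where the cause is not named below, the cause was not tested.

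Against a minimum change of 1.5-fold 978 genes passed in the main comparison, since that test asks more of each gene. With the 2 libraries left out the counts were 4717 for all libraries, 2728 in males, 2368 in females and 1 for the sexes in leukemia. DESeq2 gave 2053 genes in males, 2359 in females, 23 for the interaction, 34 for the sexes without leukemia and 120 with it. Leaving out each library in turn gave 513 to 2087 genes in males, 504 to 1773 in females, and 0 to 3 in each sex comparison with edgeR. With an estimated correlation 0 lists passed for the leukemic effect and 0 for the interaction, where fry also gave 0.

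Reversed directions, counted as above, were all in the interaction of lists that had not passed. The oxidative phosphorylation list (interaction) reversed without female leukemic replicate 1, at an adjusted p of 0.0422, within 0.0129 to 0.704 over the single libraries left out. The marrow resident and erythroblastic island macrophage list (interaction) reversed without male non-leukemic replicate 3 (0.0236, within 0.0236 to 0.995) and with the 2 libraries left out (0.000313), as did the MHC class II presentation list (interaction) (0.000270) and the lipid and cholesterol handling list (interaction) (0.0143).

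With replicate number as a block, 2509 genes passed in the main comparison, 932 in males and 1057 in females, and 13 and 11 lists. Numbers did not pair the libraries: 18 same-number pairs correlated at -0.113 to 0.0782 after group means were removed, none above 0.1, and 7 were the best match of their library. At total counts of 16911827 to 30014855, 0 counts of Hcar1 or of any gene allow up to 0.177 CPM.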

Other observations

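Some of the falls shared by both sexes were in genes of none of the fixed lists, and whether they belong to the erythroid fall was not tested. St3gal5, which makes the ganglioside GM3, fell by 2.72 ± 0.15 on the log2 scale (SE, adjusted p = 5.07e-07), from 234 ± 42.5 to 37.5 ± 7.36 CPM (SD, n = 6). The ubiquitin ligase gene Mkrn1 fell by 1.65 ± 0.09 (adjusted p = 5.70e-07) and Smox, which oxidizes spermine, by 2.35 ± 0.17 (adjusted p = 2.76e-06). Among rises of lymphocyte genes, the granzyme gene Gzmb went from 12.3 ± 2.99 to 152 ± 42.8 CPM (3.53 ± 0.24, adjusted p = 1.88e-06), and Lat from 14.3 ± 2.12 to 84.2 ± 15.7 CPM (2.47 ± 0.13, adjusted p = 4.08e-07).

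Summed CPM of 4 Y-linked genes was 102 to 183 in the male libraries. In female non-leukemic replicates 1 to 3 it was 0, 2.25 and 0, and in female leukemic replicates 1 to 3 it was 5.2, 1.42 and 14.9, which is 3.48%, 0.953% and 9.96% of the male mean. Xist was at 28.8 to 41.6 CPM in females, and at 3.19 CPM in male leukemic replicate 1, 9.35% of the female mean. In females the leukemic effect on Kdm5d was 8.38 on the log2 scale (adjusted p = 0.0343). The labels do not give the sex of the donor of the leukemic cells. Whether these traces come from the transplanted cells or from mixing of libraries was not tested, so neither the Kdm5d effect nor the smaller Y-linked differences in leukemic libraries are read as a change of expression.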
